A study of Arabidopsis thaliana with 20 samples.

How the data were processed

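Arabidopsis thaliana unopened flower buds were sampled at approximately 4 weeks of growth in 16 h light and 8 h dark. The 20 libraries fall into 10 groups of 2: NAD capture, total RNA and polyA RNA in Col-0 and dxo1, GMUCT in dxo1, and small RNA in Col-0, dxo1 and dxo1 rdr6. Per the labels, RNA was extracted with Qiazol and the miRNeasy kit and read as 50 nt single-end strand-specific reads. The authors named cutadapt, STAR 2.4.2a, HTSeq and the TAIR10 genome build in their processing notes, without settings. The deposited gene tables hold raw counts per gene for 28775 genes (27416 in GMUCT), with 5 HTSeq special entries for reads not assigned to a gene. Those entries held 91.8 to 96.1% of reads in the NAD capture libraries, 90.8 to 91.2% in total RNA, 20.3 to 21.8% in polyA RNA and 18.2 to 28.3% in GMUCT, and include reads with several matches, so genes with near-identical copies are counted incompletely. The deposited small RNA tables hold raw counts per transcript model, strand and length from 19 to 25 nt. Which tool made them is not given in the sources used here.

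Identifiers were matched to the RefSeq annotation of TAIR10.1 for symbols and gene types, for 28009 of 28775 genes and 26675 of 27162 transcripts. That table holds no positions or lengths, so no gene length, coordinate or coverage is given. Small RNA counts were summed over lengths and strands, a transcript missing from a table counting as 0. Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr (minimum count 10), scaled by TMM factors and tested with the quasi-likelihood F test, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 on the adjusted p. The 8 NAD capture and total RNA libraries formed 1 fit, which gave NAD capture over total RNA in each genotype, dxo1 over Col-0 in total RNA, and the interaction, the difference between the genotypes in the log2 ratio of capture to total RNA. The 4 polyA libraries formed a second fit, the GMUCT libraries with all polyA libraries a fit of 6, and the 6 small RNA libraries the last. This makes 9 comparisons. Tests are two-sided. With 2 libraries per group, no permutation of labels could pass the threshold, so none was run. Replicate numbers were not treated as pairs: the correlation across genes of the replicate differences of 2 groups of an assay was close to 0 except for polyA RNA and GMUCT in dxo1, at 0.538, so those libraries may be linked by number, and high DXO1 recurs under number 1 in 4 assays of dxo1.

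Before the data were examined, 20 gene lists were fixed from textbook knowledge: the target and helper gene pair, TAS loci, phased siRNA sources, the small RNA pathway, RNA decay, NAD metabolism, nuclear photosynthesis, chlorophyll synthesis, plastid transcription, cytosolic ribosomal proteins, floral organ identity, tapetum and pollen wall, late pollen and sperm, salicylic acid and defence, abscisic acid and abiotic stress, heat shock, microRNA genes, ribosomal RNA, plastid-encoded and mitochondrion-encoded genes. Lists with at least 5 tested members were tested with camera of limma 3.58.1 (preset correlation 0.01) on log2 CPM with a prior count of 2, with an estimated correlation and fry beside it, adjusted over the lists of a comparison. The genes called higher in NAD capture were tested in the other assays in the same way. Overlaps are given with the number that independent lists of the same sizes would share. The genes named were chosen by a rule fixed at the same time: DXO1 and RDR6; the 6 largest rises and 6 largest falls among passing genes that are annotated as protein-coding or carry a symbol and lie above the median level (no organelle gene has such an annotation or a symbol in the table used, so these enter by their lists alone), with both libraries of 1 group above both of the other; and from each list described up to 4 passing members of lowest p, or, if none passed, its 2 members of highest level. A fold against a group without counts is a lower bound against a floor of 3 counts over the group.

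Libraries of a group were checked not to be copies of each other: chi-square per degree of freedom between them lay between 2.26 and 33.7, over genes with a summed count of at least 20. The tests were tested on simulated data with planted changes. On those, lists of 30 genes changed 1.5-fold were found by camera in each of the 9 comparisons and with an estimated correlation in 2. Each gene was drawn independently there, without the correlation between genes of real lists. The simulation therefore cannot tell which of both list tests to trust on the data. It does show that the test with an estimated correlation missed such lists in most comparisons, even with independent genes. The fits leave 2 to 4 residual degrees of freedom. A list that fails that test is thus not shown to be unchanged. Alternatives were DESeq2 size factors, upper-quartile factors, library totals alone, DESeq2 1.42.0 in place of edgeR, no filter on low counts, the replicate number as a block, organelle and ribosomal RNA genes removed, fits of the compared groups alone, polyA RNA in place of total RNA, single length classes and each library left out in turn. Others were chosen after seeing the data: all dxo1 replicate 1 libraries left out, the even counts of dxo1 rdr6 halved, lengths from 19 to 24 nt, and transcripts listed in all 6 small RNA tables. Organelle genes and TAS loci are not in the small RNA tables, so these were not tested there.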

Results

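Unopened flower buds of Arabidopsis thaliana, harvested at approximately 4 weeks, were profiled in 20 libraries that form 10 groups of 2. The genotypes were Col-0, the laboratory reference line, the mutant dxo1 and the double mutant dxo1 rdr6. DXO1 belongs to the DXO/Rai1 family of enzymes that remove non-canonical caps, such as NAD, from the 5′ end of RNA. RDR6 is an RNA-dependent RNA polymerase that turns single-stranded RNA into the double-stranded precursor of small interfering RNAs. NAD capture, total RNA and polyA RNA were sequenced from Col-0 and dxo1. GMUCT, which reads the 5′ ends of uncapped and cleaved polyadenylated RNA, was run on dxo1, and small RNA on all 3 genotypes. Counts assigned to genes came to between 1144896 and 3178702 per NAD capture library, 2576448 and 8309456 per total RNA library, and 10100250 and 16833010 per polyA library. The GMUCT libraries held 30883266 and 19769742 counts. Small RNA libraries ranged from 137603 in dxo1 replicate 2 to 4087476 in Col-0 replicate 2, so values of that dxo1 library carry the largest counting error. CPM stands for counts scaled to a common library total, with TMM factors except for the targeted genes in single libraries. Each ± beside CPM is an SD with n = 2 libraries. Each SE is approximate: the absolute log2 fold change over the square root of the F value of its test. The labels do not say that the libraries of a group came from separate plants, so the p-values measure the spread between libraries, and a mock capture was not analysed here. Numbers after a gene symbol in parentheses are log2 fold changes unless named otherwise.

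The targeted genes were read first in every library. DXO1 (AT4G17620) went against the label in replicate 1 of dxo1: it stood at 511 CPM in total RNA and 509 in polyA RNA, 19-fold and 10.5-fold the Col-0 mean. Replicate 2 lay below Col-0, at 0.345 and 0.395 times its mean. In GMUCT the pair of libraries held 1549 and 19.8 DXO1 CPM, and in small RNA 4618 and 36.3, the last from 5 counts. NAD capture held 23.9 and 23.7 in dxo1, between the Col-0 values of 10.5 and 33.8. RDR6 (AT3G49500) stood at 7.18 and 4.51 small RNA CPM in dxo1 rdr6, against 3.37 and 4.89 in Col-0. Small RNA counts on RDR6 do not measure its transcript, so they do not check the rdr6 label. The groups keep their labels, and each dxo1 group in total RNA, polyA RNA, GMUCT and small RNA holds a replicate 1 library with high DXO1.

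**Figure D1:**
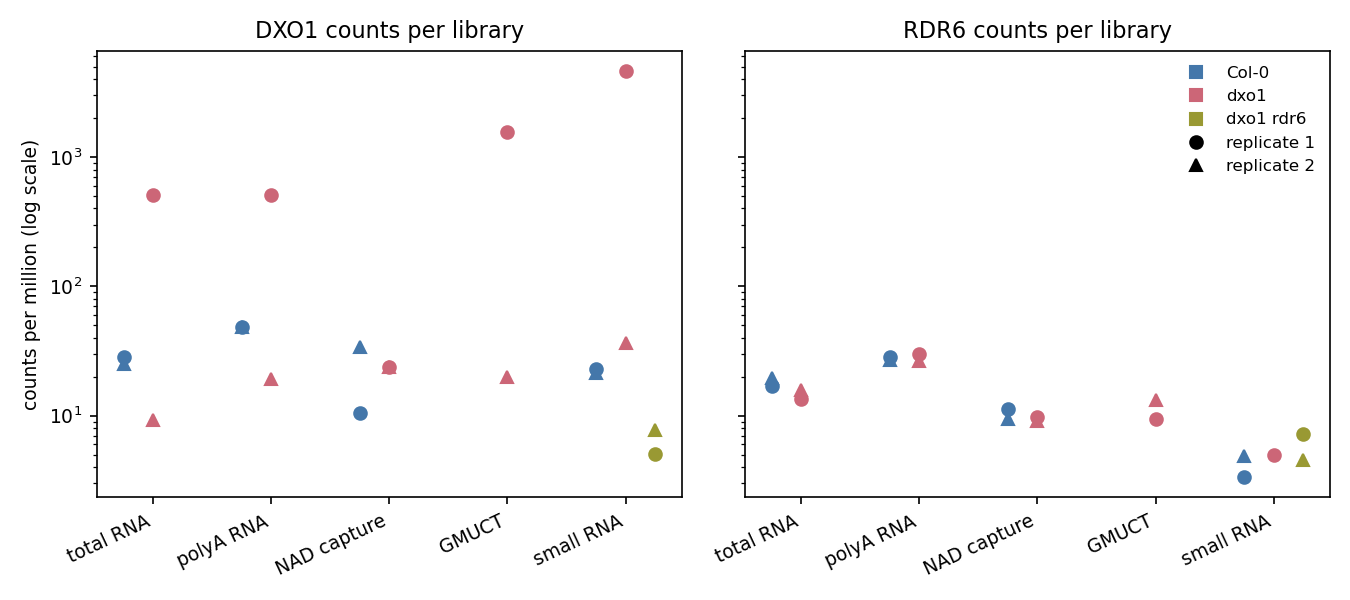
DXO1 (left) and RDR6 (right) in each library, as CPM on a log axis, by assay; colours give the genotype, circles replicate 1 and triangles replicate 2. DXO1 of dxo1 replicate 1 reaches 511 in total RNA and 4618 in small RNA, and the dxo1 small RNA replicate 2 library, with 0 RDR6 counts, is not drawn on the log axis of RDR6.

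To see which transcripts NAD capture enriches in Col-0, captured RNA was set against total RNA of the same genotype. Of the nuclear genes for photosynthesis proteins, 19 of 36 were higher in capture and 2 lower (20 and 2 adjusted over the list alone), with a median log2 fold change of 1.00. PSBX, a small photosystem II subunit, had 574 ± 125 CPM in capture and 49 ± 13.2 in total RNA (log2 fold change 3.54 ± 0.315 SE, adjusted p = 5.34e-04), and PSBW (2.70), PSAH2 (2.69) and PSAO (2.30), subunits of both photosystems, were higher as well. Genes of the small RNA pathway lay on the opposite side, 13 of 23 lower and 0 higher (14 and 0 adjusted over the list alone), among them the Dicer-like genes DCL2 (log2 fold change -1.98 ± 0.266 SE, adjusted p = 0.00133) and DCL3 (-1.76) and the Argonaute gene AGO7 (-1.66). Genes that answer to abscisic acid and abiotic stress were captured more in 9 of 25 cases (9 adjusted over the list alone), including the transcription factor DREB1A (2.2). RD29B, without a count in total RNA, was at least 30.6-fold higher against a floor of 3 counts over the group.

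In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4287 of 17718 genes passed, 2388 higher and 1899 lower in Col-0 capture. The list tests gave camera adjusted p = 2.53e-04 for photosynthesis, 2.9e-05 for the small RNA pathway and 0.00174 for abscisic acid, and adjusted p = 0.498, 0.498 and 0.615 with an estimated correlation. Of the genes that are sources of phased siRNAs, 4 of 12 were lower (5 adjusted over the list alone), led by the auxin receptor genes AFB3 (-1.07) and AFB2 (-1.48; camera adjusted p = 0.008, adjusted p = 0.413 with an estimated correlation). Tapetum and pollen wall genes, active in the nurse tissue of pollen, were lower in 9 of 25 cases and higher in 0 (10 and 3 adjusted over the list alone), such as LAP6 (-2.15; camera adjusted p = 0.0237, adjusted p = 0.616 with an estimated correlation). Late pollen genes were higher in 3 of 9 (4 adjusted over the list alone; camera adjusted p = 0.0358, adjusted p = 0.498 with an estimated correlation), with AGP6 at 2.81. MicroRNA genes were higher in 3 of 8 (4 adjusted over the list alone; camera adjusted p = 0.0205, adjusted p = 0.413 with an estimated correlation). RNA decay genes were lower in 4 of 21, XRN3 (-0.80) and HEN2 (-1.07) included, although 0 passed when adjusted over the list alone (camera adjusted p = 0.036, adjusted p = 0.498 with an estimated correlation).

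Among the largest rises in Col-0 capture, which the naming rule takes from nuclear genes above the median level, were FSD1, an iron superoxide dismutase, at log2 8.37, the small nucleolar RNA SNOR30 (7.83), the spliceosomal RNA U2.3 (7.12) and the U3 copy U3B (6.92). The plastid gene ATCG00370 stood higher still, at 9.71. Among the largest falls were AT1G27400 (-4.00) and the clock gene LHY (-3.42). RDR6 was lower in capture (-1.10, adjusted p = 0.0468), a call lost without Col-0 capture replicate 2 and without each library of another group or of Col-0 total RNA, and DXO1 did not pass (-0.58, adjusted p = 0.762). With polyA RNA in place of total RNA, AT1G27400 turned to 0.95, the photosynthesis median was 0.0638, and the photosynthesis, tapetum and late pollen lists lost their camera calls with PSAH2 and AGP6 among the genes, whereas PSBX, PSBW, PSAO and DCL2 kept theirs. U2 copies share near-identical sequence, so the value of U2.3 is uncertain. Ribosomal RNA took 39.9% of counts in Col-0 capture replicate 1 and 14.7% in replicate 2, with 95% Wilson intervals at most 0.179 percentage points wide. Without replicate 1, 7278 genes passed and the late pollen, tapetum, microRNA and phased siRNA lists lost their camera calls; without replicate 2 the late pollen, RNA decay and abscisic acid lists did, the last at a median of 0.074. Without Col-0 total RNA replicate 1 or 2, 721 and 946 genes passed, and DCL3, DREB1A, RD29B and the RNA decay list lost their calls without replicate 1, AFB2, AFB3, XRN3 and HEN2 without either. Scaling by library total alone raised the median log2 fold change of all genes from 0.0634 to 0.367 and the share of higher calls from 55.7% to 81.8% of 2574.

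The same comparison in dxo1 asked which transcripts were captured in the mutant. Photosynthesis genes were again higher, 21 of 36 against 2 lower (21 and 2 adjusted over the list alone), with a median of 0.85. PSBX reached 732 ± 27.9 CPM in capture against 37.6 ± 7.15 in total RNA (log2 fold change 4.29 ± 0.325 SE, adjusted p = 1.25e-04), and PSBW stood at 3.64 and PSAO at 2.98. Small RNA pathway genes were lower in 12 of 23 cases (13 adjusted over the list alone), among them AGO7 (log2 fold change -2.01 ± 0.27 SE, adjusted p = 6.35e-04), DRB4 (-1.75) and DCL4 (-1.82). The arabinogalactan protein gene AGP1 (5.61) and SNOR30 (6.65) were among the highest, LHY (-4.94) and AT1G27400 (-5.04) among the lowest. Tapetum genes, lower in Col-0 capture, were higher in 8 of 25 and lower in 1 (8 and 1 adjusted over the list alone), with GRP14 at 2.25 and A9 at 2.33. The median difference of the list between the genotypes was 1.06 (camera adjusted p = 8.83e-11, adjusted p = 0.995 with an estimated correlation). In total RNA, the reference of that ratio, the list was lower in dxo1 than in Col-0, at a median of -1.27. The difference in ratio is therefore not by itself a gain in capture.

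In dxo1 capture 6471 of 17718 genes passed, 3256 higher and 3215 lower. Camera gave adjusted p = 1.04e-05 for photosynthesis and 5.34e-04 for the small RNA pathway, both adjusted p = 0.594 with an estimated correlation. With polyA RNA in place of total RNA the photosynthesis median was 0.0455 and that call was lost, AT1G27400 turned to 0.24 and GRP14 and A9 lost their calls. DXO1 was lower in capture (log2 fold change -4.12 ± 1.23 SE, adjusted p = 0.024), which turned to 0.68 without dxo1 total RNA replicate 1, the library with high DXO1, and did not pass without either dxo1 capture library. RDR6 was lower too (-1.30, adjusted p = 0.0107), not without either dxo1 capture library or dxo1 total RNA replicate 2. No list test passed for tapetum genes (camera adjusted p = 0.0992) or plastid-encoded genes (18 higher and 38 lower of 97, 18 and 39 adjusted over the list alone, camera adjusted p = 0.0506). That plastid list had a median of -0.90 but a mean of 0.0033, so its members went both ways. Floral organ identity genes were higher in 7 of 14 and lower in 3 (8 and 3 adjusted over the list alone), with the nectary and carpel gene CRC at 2.75 and SEP3 at -0.84, whose call any left-out dxo1 library ended (camera adjusted p = 0.171). Mitochondrion-encoded genes were higher in 14 of 40 and lower in 9 (14 and 9 adjusted over the list alone, camera adjusted p = 0.209). Without dxo1 capture replicate 1 or 2, 2229 and 3321 genes passed (A9 and DCL4 lost their calls without replicate 1), and without dxo1 total RNA replicate 1 or 2, 3677 and 2269. Leaving out both replicate 1 libraries ended every call, 0 in edgeR with 3856 genes at an unadjusted p under 0.05, and scaling by library total alone put 88.9% of the calls on the higher side against 50.3%, with the median of all genes at 0.719.

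The genotypes were then compared directly, by testing whether the capture over total RNA ratio differed between dxo1 and Col-0. Capture of 1803 genes was higher in both, of 2388 in Col-0 and 3256 in dxo1, where independent lists would share 439. For lower genes the shared number was 1490 of 1899 and 3215, against 345. Across 17718 genes, which are not independent replicates, the folds correlated with Pearson's r = 0.797 and Spearman's rho = 0.782. The edgeR interaction test called 0 genes, with 1332 at an unadjusted p under 0.05 and a lowest adjusted p of 0.269, and DESeq2 called 13. On simulated counts the same test found 70% of genes changed 8-fold, 28% of those changed 4-fold and 2% of those changed 2-fold. Most 2-fold differences were thus not detectable with this number of libraries, their spread and their depth, which were not varied. Tapetum genes such as ATA20 (difference 1.02 ± 0.535 SE, adjusted p = 0.687) and the stress gene ERD14 (-0.88, adjusted p = 0.679) did not pass over all genes. Adjusted over the list alone, 3 of 25 tapetum genes and 1 of 14 floral organ identity genes passed as higher. As lower passed 2 of 25 abscisic acid genes and 2 of 11 ribosomal RNA genes. DXO1 stood at -3.54 (adjusted p = 0.67) and RDR6 at -0.21 (adjusted p = 0.944). Without Col-0 capture replicate 1 or 2 the count became 187 and 1706, and without a filter on low counts 287.

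In total RNA, dxo1 was compared with Col-0 to see which transcripts differ between the genotypes. Of the salicylic acid and defence genes 4 of 22 passed as higher in dxo1 (12 adjusted over the list alone), with a median of 1.41 for the list (camera adjusted p = 2.27e-09, adjusted p = 0.647 with an estimated correlation). The pathogenesis-related glucanase gene PR2 went from 1.2 ± 0.19 to 48 ± 24.7 CPM (log2 fold change 5.30 ± 0.98 SE, adjusted p = 0.0404), and WRKY46 (3.89), the lipase-like regulator gene PAD4 (3.47) and WRKY70 (1.95) rose as well. Lower in dxo1 were 7 of 25 tapetum and pollen wall genes (19 adjusted over the list alone; camera adjusted p = 9.16e-18, adjusted p = 0.221 with an estimated correlation) and 1 of 9 late pollen genes (6 adjusted over the list alone; camera adjusted p = 1.04e-08, adjusted p = 0.221 with an estimated correlation). EXL6, a pollen coat lipase gene, dropped from 341 ± 5.29 to 71.9 ± 13.1 CPM (log2 fold change -2.25 ± 0.293 SE, adjusted p = 0.0317), and GRP14 (-2.19) and AGP6 (-3.09) also fell. Of the small RNA pathway, DCL3 fell (log2 fold change -1.48 ± 0.29 SE, adjusted p = 0.0445), 1 of 23 genes against 3 lower and 1 higher when adjusted over the list alone.

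Between genotypes in total RNA 175 of 17718 genes passed, 72 higher and 103 lower. Cytosolic ribosomal protein genes had a median of 0.53 with 0 of 35 called (7 adjusted over the list alone; camera adjusted p = 9.01e-09, adjusted p = 0.176 with an estimated correlation). NAD metabolism genes had 0 of 18 called (3 adjusted over the list alone, camera adjusted p = 0.748), and the Nudix hydrolase gene NUDT7 was at 1.22, adjusted p = 0.131. DXO1 itself did not pass (log2 fold change 3.32 ± 1.17 SE, adjusted p = 0.203). Each call named here was lost without some single library: edgeR called 0 genes without either dxo1 capture library, either Col-0 total RNA library or dxo1 total RNA replicate 1, and 1 without replicate 2, with between 1271 and 2271 genes at an unadjusted p under 0.05. It was 2220 and 2182 without Col-0 capture replicate 1 or 2, 2357 when the total RNA libraries alone were fitted, 285 in DESeq2 and 0 in edgeR with library total scaling or without the dxo1 replicate 1 libraries (1567 and 1288 at an unadjusted p under 0.05).

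PolyA RNA gave a deeper view of the same contrast. Defence genes rose, 20 of 26 with 1 lower (21 and 1 adjusted over the list alone), at a median of 1.32. PR2 rose from 1.23 ± 0.476 to 78.4 ± 47.5 CPM (log2 fold change 6.04 ± 0.579 SE, adjusted p = 0.00137), the chitinase-like PR4 by 3.27, WRKY46 by 2.86 and NIMIN1, whose protein binds the salicylic acid receptor NPR1, by 2.32. Late pollen genes fell in 10 of 10 (10 adjusted over the list alone), with a median of -1.84, including the pollen tube receptor kinase gene ANX2 (log2 fold change -2.16 ± 0.193 SE, adjusted p = 0.00119) and the pectin methylesterase gene VGD1 (-1.89). Tapetum genes fell in 12 of 25 with 1 higher (the same numbers adjusted over the list alone), among them EXL6 (-2.36) and GRP16 (-2.23). Cytosolic ribosomal protein genes rose by a small amount in 25 of 35 with 1 lower (28 and 1 adjusted over the list alone), at a median of 0.49, for example RPL27AC (log2 fold change 0.92 ± 0.0831 SE, adjusted p = 0.00121).

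**Figure D2:**
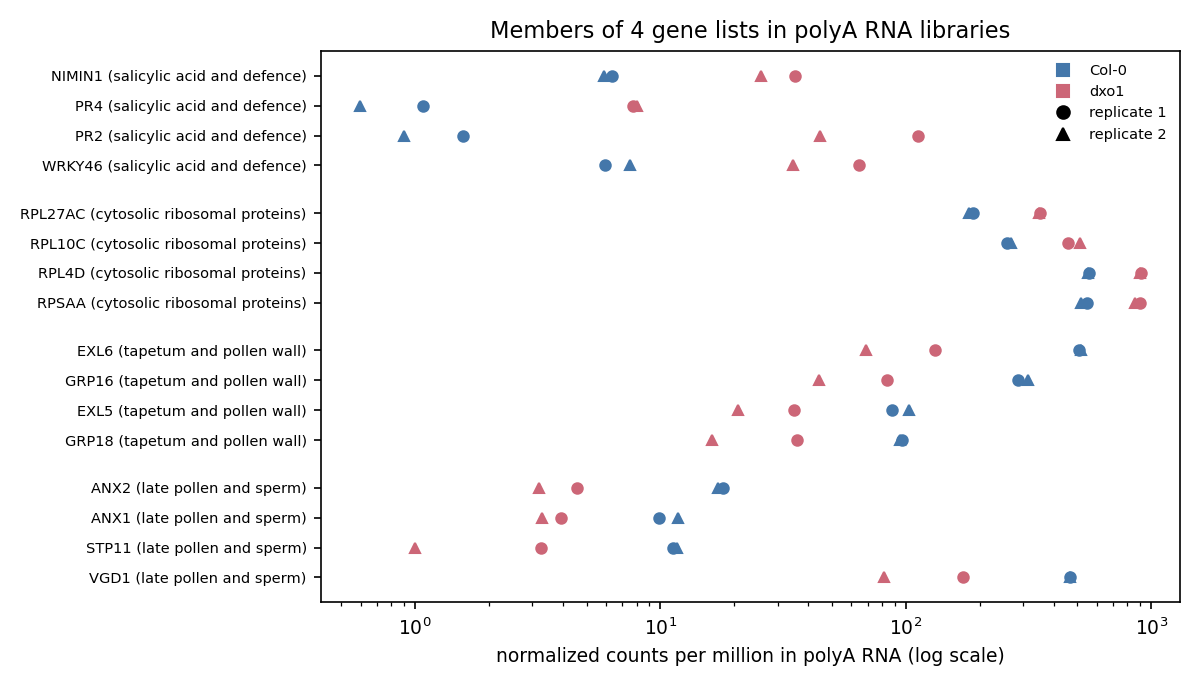
Normalised CPM in polyA RNA (log axis) of the named members of 4 gene lists, one line of points per gene; colours give the genotype, circles replicate 1 and triangles replicate 2. PR2 moves from a mean of 1.23 in Col-0 to 78.4 in dxo1, and EXL6 from 513 to 100.

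In polyA RNA 5932 of 19730 genes passed, 3075 higher and 2857 lower, of which 747 and 1142 changed at least 2-fold. The largest falls under the naming rule were in TPS10, a terpene synthase gene (log2 fold change -3.52 ± 0.258 SE, adjusted p = 8.26e-04), GPAT5, an acyltransferase gene of suberin synthesis (-3.16), and the cytochrome P450 gene CYP76C3 (-3.04), and GRP-3 (2.4) and EID1 (2.18) were among the largest rises after PR2. Heat shock genes rose in 4 of 5 (5 adjusted over the list alone), HSP90.1 by 0.89. TAS loci, the non-coding sources of trans-acting siRNAs, had a median of -0.72 with 0 of 7 called over all genes or the list alone. Cold and drought genes fell in 5 of 26 and rose in 2 (the same numbers adjusted over the list alone; camera adjusted p = 0.387), COR47 standing at -1.66 and RD29B at 3.20. NAD metabolism genes rose in 5 of 18 and fell in 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.646), the Nudix hydrolase gene NUDT6 by 2.81 and PARP2 by 0.94. Within the small RNA pathway AGO2 (0.94), HYL1 (0.93) and SE (0.52) rose, 3 of 23 over all genes and adjusted over the list alone. Chlorophyll synthesis genes rose in 2 of 13 and fell in 1, also when adjusted over the list alone (camera adjusted p = 0.966). Camera gave adjusted p = 1e-06 for defence, 1e-06 for ribosomal proteins, 3.72e-05 for late pollen, 0.0179 for tapetum, 0.0119 for heat shock and 0.0191 for TAS loci, and adjusted p = 0.783 with an estimated correlation for all of these but tapetum, at 0.854.

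Of the genes higher in dxo1 total RNA, 69 of 72 were also higher in polyA RNA, where independent lists would share 11.5, and of the lower genes 84 of 102 against 15.3. Across 17537 genes the folds in both assays, which share no library, correlated with Pearson's r = 0.754 and Spearman's rho = 0.688. High DXO1 in dxo1 replicate 1 of both assays leaves open that they share plant material. The agreement would then not be independent. DXO1 did not pass in polyA RNA (log2 fold change 2.41 ± 1.12 SE, adjusted p = 0.147) and had replicate 1 and 2 on opposite sides of Col-0, and RDR6 stood at 0.013, adjusted p = 0.937. Without Col-0 polyA replicate 1 or 2, 670 and 1264 genes passed, and VGD1 and HYL1 lost their calls without replicate 1, HSP90.1, SE, NUDT6, PARP2 and RD29B without either. On simulated polyA counts the test found 80% of 2-fold changes, with 30 false among 201 calls, a larger share than the threshold of 0.05.

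GMUCT and polyA RNA of dxo1 were compared to see which transcripts have many uncapped or cleaved ends for their level. Most photosynthesis genes had few for their abundance: 24 of 36 were lower in GMUCT and 7 higher (25 and 7 adjusted over the list alone), at a median of -1.26. The light-harvesting gene LHCB1.3 had 192 ± 15.3 CPM in GMUCT and 4250 ± 388 in polyA RNA (log2 fold change -4.46 ± 0.148 SE, adjusted p = 2.54e-06), and LHCA2 stood at -4.13. LHCB1 copies are near-identical, so their separate values are uncertain. Plastid-encoded genes were lower in 42 of 70 and higher in 20 (43 and 20 adjusted over the list alone), such as ATCG00020 (-6.14). Small RNA pathway genes were lower in 15 of 23 and higher in 2 (the same adjusted over the list alone), with HST at -1.50 and the RNA helicase gene SDE3, on the other side, at 2.27.

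Between GMUCT and polyA RNA 13032 of 20117 genes passed, 6585 higher and 6447 lower, and each left-out library kept the number between 11505 and 12910. AT1G31835 (5.0) and AT1G56660 (4.5) were among the largest rises under the naming rule, and AGP23 (-5.38) and LHCB1.3 among the largest falls of nuclear genes. Plastid transcription genes, which encode the nuclear-made plastid polymerase and sigma factors, were higher in 7 of 8 and lower in 1 (the same adjusted over the list alone), SIG2 by 1.68, though the list test did not pass (camera adjusted p = 0.0628). Ribosomal protein genes went both ways, 19 of 35 lower and 8 higher (20 and 10 adjusted over the list alone), from RPSAA (-4.04) to RPS15AA (3.42). RNA decay genes were lower in 11 of 21 and higher in 7 (the same adjusted over the list alone; camera adjusted p = 0.347), with the exonuclease gene XRN3 at -2.31 and the decapping gene DCP2 at 1.35. Camera gave adjusted p = 0.00123 for photosynthesis, 0.00235 for plastid-encoded and 0.0151 for small RNA pathway genes, and adjusted p = 0.917, 0.291 and 0.571 with an estimated correlation. GMUCT reads ends and polyA libraries read whole molecules, so the difference between assays also enters each fold, and on simulated counts 24 of 171 calls were false. DXO1 stood at 1.75, adjusted p = 0.379 and RDR6 at -1.21, adjusted p = 2.71e-04. A GMUCT library of Col-0 was not analysed here, so whether these ratios depend on DXO1 was not tested.

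Small RNA counts were given per transcript model, strand and length from 19 to 25 nt. In Col-0, 24 nt reads, the length of heterochromatic siRNAs, took 55.3% and 55.9% of counts, and in dxo1 50.7% and 43.8%. The 21 nt class, that of most microRNAs and phased siRNAs, held 8.52% and 9.27% in Col-0 and 13.2% and 14.3% in dxo1. Both dxo1 rdr6 libraries stood apart: 25 nt reads took 92.1% and 88% of their counts, 24 nt reads 4.64% and 7.51%, and the pair of most abundant transcripts 43.8% and 50.5%. Each count of both dxo1 rdr6 libraries was even, with 0 odd values against 91230 in Col-0 replicate 1. These shares have 95% Wilson intervals at most 0.524 percentage points wide, for counting error alone. The comparisons with dxo1 rdr6 set libraries of unlike length composition side by side.

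**Figure D3:**
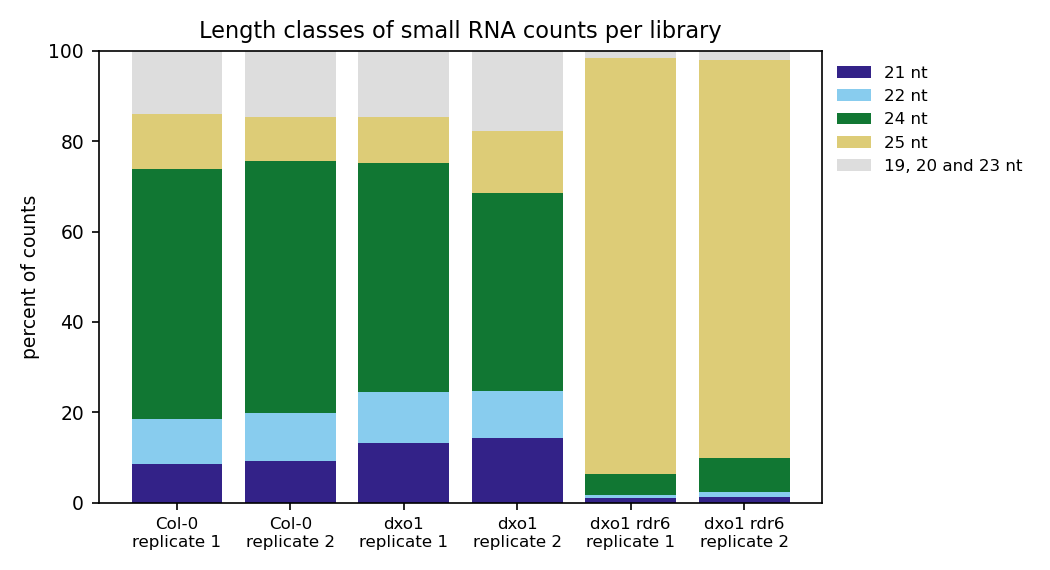
Percent of small RNA counts in each length class, one bar per library. The 25 nt class fills 92.1% and 88% of the dxo1 rdr6 bars and from 9.66% to 13.6% of the other four, in which 24 nt is the largest class.

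Small RNA of dxo1 was compared with Col-0 to find transcripts that gain or lose small RNA. Small RNA of bZIP2 (AT2G18160), a basic leucine zipper transcription factor gene, rose from 22.1 ± 1.83 to 3026 ± 678 CPM (log2 fold change 7.10 ± 0.903 SE, adjusted p = 4.84e-05). Of its counts in dxo1 replicates 1 and 2, 8272 of 8460 and 1008 of 1020 were antisense, as were most in Col-0. EXO, a cell expansion gene (6.73), GAE6, a pectin precursor epimerase gene (5.67), and BCS1, an AAA-type ATPase gene (5.29), also gained small RNA. Among defence genes 5 of 19 gained small RNA and 0 lost it (6 and 1 adjusted over the list alone), including PAD4 (log2 fold change 3.88 ± 0.631 SE, adjusted p = 4.02e-04), WRKY46 (3.45), EDS1 (2.28) and WRKY70 (2.29). The list test did not pass (camera adjusted p = 0.194, adjusted p = 0.922 with an estimated correlation). Losses were seen in MPC (-4.77) and in the auxin receptor genes AFB3 (log2 fold change -2.42 ± 0.566 SE, adjusted p = 0.00982) and AFB2 (-1.96), 2 of the 17 tested sources of phased siRNAs (3 adjusted over the list alone, camera adjusted p = 0.194).

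Between dxo1 and Col-0 small RNA, 815 of 15358 transcripts passed, 354 higher and 461 lower, around a median log2 fold change of -0.305. The direction depends on single libraries, on the groups fitted, on the scaling and on the lengths counted. In a fit of the Col-0 and dxo1 libraries alone, 1170 of 1819 calls were higher and 649 lower, around a median of 0.0352. The excess of lower calls thus came with the dxo1 rdr6 libraries in the fit. Among 21 and 22 nt counts 399 were higher and 647 lower, around a median of -0.675. From 19 to 24 nt 742 were higher and 356 lower, around 0.0827. Without dxo1 replicate 1, 64 were higher and 1071 lower, around a median of -1.10, and without dxo1 replicate 2, 627 and 281. With all libraries 43.4% of calls were higher with TMM, 53.8% with upper-quartile factors and 88% of 1499 with the library total, where the median was 0.527. PAD4, WRKY46, EXO and bZIP2 kept their calls under each of these scalings, and AFB2 lost its call with the library total. With the dxo1 rdr6 counts halved 1822 of 11059 passed, 63.9% of them higher. Without Col-0 small RNA replicate 1 or 2, 116 and 20 transcripts passed, and bZIP2, EXO, GAE6, BCS1, WRKY46, EDS1, WRKY70, AFB2, AFB3 and DXO1 lost their calls each time, PAD4 and MPC without replicate 2. Without dxo1 rdr6 replicate 2 the number was 1972. Without dxo1 replicate 1, PAD4, WRKY46 and EDS1 lost their calls and WRKY70 turned to -6.26. In replicate 2, the shallow library, the 21 and 22 nt counts were 1 and 0 for PAD4, out of 1 of all lengths. WRKY70 held 0 counts there, against 6 and 8 in the larger Col-0 libraries, so its -6.26 does not show a loss. DXO1 passed (log2 fold change 6.05 ± 1.33 SE, adjusted p = 0.00593) on the counts of replicate 1 and stood at -1.18 without it. Of the photosynthesis, ribosomal protein and tapetum lists 0 genes were called over all genes, with LHCA2 at -1.69, adjusted p = 0.188, and RDR6 stood at -0.70, adjusted p = 0.589.

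To see which small RNA of dxo1 depends on RDR6, dxo1 rdr6 was compared with dxo1. Small RNA of the source genes of phased siRNAs fell in 13 of 17 (13 adjusted over the list alone), at a median of -3.53 (camera adjusted p = 1.04e-07, adjusted p = 0.67 with an estimated correlation). Within 21 and 22 nt counts that median was -1.51, with 10 lower and 1 higher, a smaller change than over all lengths. All 1928 transcripts tested within those lengths had a median of -0.469. The pentatricopeptide repeat gene AT1G63330 fell from 96.2 ± 38.9 to 2.57 ± 0.563 CPM (log2 fold change -5.26 ± 0.592 SE, adjusted p = 4.73e-07), and its relatives AT1G63070 (-4.73), AT1G63130 (-4.55) and AT1G63400 (-4.38) fell too. These genes form a family of close copies, and how reads with several matches were counted is not given in the sources used here, so their separate values are uncertain. The defence list went both ways, 6 of 19 lower and 4 higher (the same adjusted over the list alone; camera adjusted p = 0.89, adjusted p = 0.99 with an estimated correlation). Of the genes named above with more small RNA in dxo1, PAD4 at -3.62, WRKY46 at -2.47 and EDS1 at -1.94 were lower, and WRKY70 did not pass. SNC1, an immune receptor gene of the RPP5 cluster, fell by 2.69. The higher ones, CYP71A13, WRKY18, WRKY33 and ADR1, are named after their values were seen. Ribosomal protein genes were higher in 20 of 34 and lower in 1 (25 and 1 adjusted over the list alone, camera adjusted p = 5.6e-05, adjusted p = 0.67 with an estimated correlation). Photosynthesis genes were higher in 15 of 36 and lower in 1 (the same adjusted over the list alone, camera adjusted p = 2.58e-06, adjusted p = 0.67 with an estimated correlation), RBCS2B by 2.57. Of the RBCS2B counts in dxo1 rdr6, 768 of 806 and 664 of 736 were 25 nt long, the class that held most counts of both libraries. Its rise is therefore not separated from that change in length composition.

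Against dxo1, 5560 of 15358 transcripts passed, 1984 higher and 3576 lower. Fewer higher calls came from DESeq2, with 287 higher and 2436 lower, and from a fit of the compared groups alone, with 626 and 2870. AT2G07734 (7.87) and AT1G31835 (6.39) were among the largest rises under the naming rule, and AT1G53265, without a count in dxo1 rdr6, was at least 276-fold lower against a floor of 3 counts over the group. Of the 354 transcripts higher in dxo1 than in Col-0, 287 were lower again in dxo1 rdr6, where independent lists would share 82.4, and of the 461 lower ones 10 were higher again, against 59.6. Both comparisons use the dxo1 libraries, so a chance high value there raises a transcript in the one and lowers it in the other. In 20 simulations of unchanged groups at most 2 transcripts passed in the first comparison and 0 were shared, too few calls to say how many of the 287 would be shared for that reason. Within 21 and 22 nt counts, 39 of the 239 that could be tested passed as lower and 11 as higher, with a median of -0.508 against -2.28 over all lengths. Among all 1928 transcripts tested within those lengths, 356 passed as lower and 178 as higher, at a median of -0.469. Within 21 and 22 nt the set thus moved about as far as transcripts in general. From 19 to 24 nt it moved further, at a median of -1.18 against -0.647 for all transcripts tested. Scaling within a length class removes a loss that the whole class shares. These fits therefore cannot tell composition from such a loss. Tapetum genes were lower in 4 of 22 (4 adjusted over the list alone; camera adjusted p = 0.0481, adjusted p = 0.67 with an estimated correlation), and plastid transcription genes higher in 2 of 8 (1 adjusted over the list alone; camera adjusted p = 0.0481, adjusted p = 0.67 with an estimated correlation). With the dxo1 rdr6 counts halved 5732 of 11059 passed, 2150 higher and 3582 lower. Among 21 and 22 nt counts alone 534 transcripts passed, among 24 nt counts 1016 and from 19 to 24 nt 1739, and in the last AT2G07734 turned to -0.21, AT1G31835 lost its call, and the ribosomal protein median turned to -0.0473 and the tapetum median to 0.481. The phased siRNA list lost its camera call among 24 nt counts, where AT1G63070 turned to 2.02, and SNC1 lost its call there and among 21 and 22 nt counts. The tapetum list also lost its camera call without dxo1 or dxo1 rdr6 replicate 2. Without dxo1 replicate 1, 1814 passed, PAD4 and DXO1 lost their calls, and WRKY46 and EDS1 turned to 0.97 and 0.060. DXO1 fell with all libraries (-8.85, adjusted p = 5.39e-05) and RDR6 stood at 0.027, adjusted p = 0.979.

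The double mutant was then set against Col-0, to see which small RNA of the reference line it had less of. Small RNA fell at most phased siRNA sources: 16 of 17 fell (16 adjusted over the list alone), at a median of -3.72 (camera adjusted p = 6.41e-09, adjusted p = 0.69 with an estimated correlation). The auxin response factor gene ARF4, a target of trans-acting siRNAs, fell from 1447 ± 132 to 15.6 ± 0.22 CPM (log2 fold change -6.53 ± 0.866 SE, adjusted p = 1.04e-06), ARF3 at -2.91 and AT1G63330 at -5.55. Tapetum genes fell in 14 of 22 (16 adjusted over the list alone), GRP18 at -5.11 and GRP14 at -3.01 (camera adjusted p = 0.00108, adjusted p = 0.638 with an estimated correlation). The defence list went both ways, 3 of 19 higher and 3 lower (the same adjusted over the list alone), with WRKY18 at 3.12 and SNC1 at -3.99 (camera adjusted p = 0.397). Ribosomal protein genes were higher in 21 of 34 and lower in 1 (25 and 2 adjusted over the list alone; camera adjusted p = 1.14e-06, adjusted p = 0.69 with an estimated correlation), while photosynthesis genes had a median of 0.45, with LHCA2 as the single gene called, at -3.77 (camera adjusted p = 0.00181, adjusted p = 0.732 with an estimated correlation).

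Here 4877 of 15358 transcripts passed, 1324 higher and 3553 lower, and in DESeq2 229 were higher and 2781 lower. AT5G05250 (6.09) and AT2G20720 (5.15) were among the highest, and AT1G53265 was at least 835-fold lower. With TMM 27.1% of the calls were higher, with upper-quartile factors 49%, and with the library total 71.3% of 9704, the median of all transcripts moving from 0.0239 to 1.09. With the dxo1 rdr6 counts halved 5872 of 11059 passed, 2933 higher and 2939 lower (49.9% higher). ARF4, ARF3 and AT1G63330 stayed lower under all 3 scalings, and GRP18 and GRP14 as well. DXO1 stood at -2.80, adjusted p = 0.0806 and RDR6 at -0.67, adjusted p = 0.381. Without Col-0 replicate 2 the number was 2810, with 5.48% higher, and without dxo1 rdr6 replicate 2 it was 7189, with 44.3% higher. Among 21 and 22 nt, 24 nt and 19 to 24 nt counts 1190, 1171 and 2462 passed. The tapetum median turned to 0.523 from 19 to 24 nt, and the phased siRNA list lost its camera call among 24 nt counts, SNC1 its call among 21 and 22 nt counts.

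Genes higher in NAD capture were then followed in the other assays, which share no library with them but may share plant material. The 2233 such genes of Col-0 that GMUCT tested had a median fold of GMUCT over polyA RNA of 0.374 (log2) against -0.0414 in other genes, with 1035 higher and 508 lower (camera adjusted p = 0.0026, adjusted p = 0.589 with an estimated correlation). Each test of this paragraph gave that same value with an estimated correlation, so none passed there. The genes called in dxo1 had a GMUCT median of 0.266 (camera adjusted p = 0.0152). In small RNA of dxo1 against Col-0, the Col-0 set stood at -0.0289 and other transcripts at -0.334 (camera adjusted p = 0.0026), the dxo1 set at -0.128 (camera adjusted p = 0.0152). Medians in dxo1 rdr6 against dxo1 were 0.316 and 0.308 (camera adjusted p = 0.0225 for both), and against Col-0 0.344 (camera adjusted p = 7.15e-04) and 0.272 (camera adjusted p = 0.0026). In polyA RNA the sets lay at -0.0511 (camera adjusted p = 0.0814) and -0.0548 (camera adjusted p = 0.0466). The call against dxo1 was lost when the sets held genes at least 2-fold higher in capture. Of the 2198 genes higher in dxo1 capture with small RNA data, 50 gained small RNA in dxo1, where independent lists would share 54.5, and for the Col-0 set 54 against 40.2.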

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

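Tests chosen only after the result was seen are those of DXO1, of a few transcripts taking the counts and of the phased siRNA sources, and the genes of the mislabelling test were chosen anew because the set first named for it, genes passing between 1 dxo1 library and Col-0, was empty. Differences between genotypes in the capture to total RNA ratio, as list medians of dxo1 minus Col-0, drew attention by the preset correlation alone: 0.249 for nuclear photosynthesis genes (camera adjusted p = 0.0222), 1.06 for tapetum and pollen wall (8.83e-11), -0.877 for abscisic acid and abiotic stress (7.68e-04), -2.28 for ribosomal RNA (0.00246) and -1.32 for plastid-encoded genes (8.83e-11), each with adjusted p = 0.995 with an estimated correlation. The plastid and photosynthesis calls ended without Col-0 capture replicate 1, in which ribosomal RNA took 39.9% of counts, and the abscisic acid median turned to 0.285 without replicate 2; the photosynthesis call also ended without dxo1 capture replicate 1, Col-0 total RNA replicate 1 or dxo1 total RNA replicate 2. The tapetum and ribosomal RNA calls held under each left-out library. For tapetum genes the total RNA reference was itself lower in dxo1, at a median of -1.27, so the ratio alone does not show a gain in capture.

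DXO1 lay above Col-0 in the dxo1 replicate 1 libraries of total, polyA and small RNA, at 17.9, 10.4 and 201 times the higher Col-0 library. Antisense small RNA of DXO1, outside the comparisons of the report, also stood out there, with a count of 5089 (1400 CPM) against 10.1 and 5.87 CPM in Col-0. Col-0 plants under a wrong label are argued against by these levels and by the 100 genes of lowest p between dxo1 replicate 2 and Col-0 in total RNA: in polyA RNA replicate 1 shifted by 1.64 and replicate 2 by 2.41, a ratio of 0.68, and 0.659 with the assays exchanged. A single plant material behind each replicate 1 library, with DXO1 captured as in Col-0, is argued against by its capture library, which held 23.9 DXO1 CPM where 421 (range 188 to 683) would follow, a ratio of 0.0569; a transcript that is captured less stays open. Reads from a vector, an insertion or another allele may also be the source, which counts per gene cannot show: 88.4% of the DXO1 small RNA counts were 21 or 22 nt long.

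The 25 nt class took 92.1% and 88% of the dxo1 rdr6 counts in replicates 1 and 2, the order kept below, and at most 13.6% elsewhere. A few transcripts are argued against as the whole cause, since without the 10 with most 25 nt counts the share was still 79.5% and 65.5%. Fragments of messenger RNA are a candidate explanation: Spearman's rho with polyA CPM across genes was higher for 25 than for 24 nt counts by 0.694 and 0.641, and 76% and 82.4% were sense, though in the other libraries rho differed by 0.44 to 0.528 too, and their sense shares at 25 nt were higher, from 87.2 to 92.7%. Composition may likewise explain why transcripts higher in dxo1 were lower again in dxo1 rdr6. Of these, 16.3% passed as lower within 21 and 22 nt (39 of 239 tested, 13.6% of all, and 11 as higher), at a median of -0.508. Within 19 to 24 nt 40.9% did (3 as higher), at a median of -1.18. All transcripts tested had medians of -0.469 (356 of 1928 lower) and -0.647 (1367 of 4569 lower) in these fits. Scaling within such lengths removes a loss that they share, so composition and a general loss are not told apart here. Composition is argued against as the whole cause for the phased siRNA sources. Their median was -3.53 over all lengths and -1.51 within 21 and 22 nt, with 10 lower and 1 higher. Loss of RDR6 activity is the biological explanation that the genotype names. It was not tested, since the dxo1 rdr6 libraries also differ in length composition and hold even counts alone.

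Photosynthesis genes were higher and small RNA pathway genes lower in capture than in total RNA in both genotypes. With polyA RNA as the reference the photosynthesis medians were 0.0638 in Col-0 and 0.0455 in dxo1, consistent with a difference set by the total RNA libraries, although PSBX, PSBW and PSAO kept their calls. The small RNA pathway medians stayed at -0.716 and -0.804, which argues against the same explanation for that list. Whether capture selects by NAD caps or by other features, such as length, cannot be judged without a mock capture and gene lengths, and no biological explanation was tested.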

How the results depend on the processing

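Alternatives chosen after seeing the data were leaving out all dxo1 replicate 1 libraries, halved dxo1 rdr6 counts, 19 to 24 nt counts and transcripts listed in all 6 tables. Leaving out a library left its group with 1, assumed to vary like the others. Over the left-out libraries 1807 values of named genes counted as unchanged, 359 lost their call, 18 gained one and 6 turned. Over the other alternatives the numbers were 2902, 255, 17 and 17. For list values these numbers were 408, 15, 25 and 2, and 605, 16, 25 and 5. Unchanged means the same side of the threshold, with the same direction if called in either fit. Left-out libraries include those of groups outside the comparison, which act through filter, scaling and spread alone. Removing organelle and ribosomal RNA genes left the small RNA fits identical. The unchanged numbers are therefore no measure of stability. The cause was not tested unless given.

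With single libraries left out, the number of genes passing ranged from 721 to 7278 for Col-0 capture, 2229 to 9622 for dxo1 capture, 0 to 1706 for the interaction, 0 to 2220 for total RNA, 670 to 8890 for polyA RNA, 11505 to 12910 for GMUCT, 20 to 1972 for dxo1 small RNA, 1814 to 7293 for dxo1 rdr6 against dxo1 and 2810 to 7189 against Col-0. Values that turned ranged from -0.943 to 1.14 for plastid-encoded genes in Col-0 capture, -5.11 to 0.68 for DXO1 in dxo1 capture, -1.14 to 0.285 for abscisic acid and abiotic stress in the interaction, -1.34 to 3.35 for DXO1 in polyA RNA, -1.18 to 7.29 for DXO1 in dxo1 small RNA, -6.26 to 2.84 for WRKY70 in dxo1 small RNA, -2.29 to 0.060 for EDS1 in dxo1 rdr6 against dxo1 and -2.96 to 0.97 for WRKY46 in dxo1 rdr6 against dxo1. DXO1 turned without the dxo1 replicate 1 library that holds its high counts. The -6.26 of WRKY70 rests on 0 counts in dxo1 small RNA replicate 2.

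Library totals alone gave 2574 genes for Col-0 capture, 0 for total RNA (edgeR; 1567 at an unadjusted p under 0.05, DESeq2 285), 1499 for dxo1 small RNA and 9704 for dxo1 rdr6 against Col-0, and the phased siRNA sources turned to 0.0554 in dxo1 capture. Without a filter on low counts 287 genes passed in the interaction and 1081 in total RNA. The replicate block gave 19 in total RNA and 382 in dxo1 small RNA. Fits of the 2 compared groups alone gave 1408 for Col-0 capture, 2357 for total RNA, 1819 for dxo1 small RNA and 3496 for dxo1 rdr6 against dxo1. DESeq2 called 13 in the interaction, 285 in total RNA, 313 in dxo1 small RNA and 2723 and 3010 for dxo1 rdr6 against dxo1 and Col-0.

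Without all dxo1 replicate 1 libraries 1024 genes passed for Col-0 capture, 0 for dxo1 capture (3856 at an unadjusted p under 0.05 in edgeR, DESeq2 on all libraries 4697), where DXO1 turned to 0.67, and 0 for total RNA (1288 in edgeR); fewer libraries, 1 per dxo1 group, stand behind these. With polyA RNA in place of total RNA, 3697 genes passed in Col-0 capture, 2481 of them called the same way against total RNA, and 6046 in dxo1 capture, 4194 of them the same way. There AT1G27400 turned to 0.95, U2.7 to 10.17, AT5G08180 to 2.83 and AT4G30993 to 1.95 in Col-0. In dxo1 AT1G27400 turned to 0.24, AT5G08180 to 1.15, AT2G35750 to 5.21, AT3G63052 to 6.17, AT-IE to 2.26 and the plastid-encoded median to 4.34.

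Counts of 21 and 22 nt gave 534 transcripts against dxo1 and 1190 against Col-0, where AT2G07734 turned to -0.036. Counts of 24 nt gave 194 for dxo1 against Col-0, 1016 against dxo1, where AT1G63070 turned to 2.02, and 1171 against Col-0, where AT1G63400 turned to 0.31. Counts of 19 to 24 nt gave 1739 and 2462. Against dxo1 AT2G07734 turned to -0.21, AT5G65860 to -1.16, ribosomal proteins to -0.0473 and tapetum and pollen wall to 0.481. Against Col-0 AT2G07734 turned to -0.62, AT5G65860 to -0.80 and the tapetum to 0.523. These sets hold fewer counts. With halved dxo1 rdr6 counts 1822 passed in dxo1 small RNA, 5732 against dxo1 and 5872 against Col-0, 2933 of these higher, with 11059 transcripts tested in each.

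With camera 37 list tests passed over the 9 comparisons, 0 with an estimated correlation (limma; 7 of 145 at an unadjusted p under 0.05) and 26 with fry; of the sets of genes higher in capture 9 tests passed with camera, 0 with an estimated correlation (limma; 0 at an unadjusted p under 0.05) and 1 with fry.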

Other observations

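Most small nucleolar and transfer RNA genes were higher in NAD capture than in total RNA in both genotypes. Of 57 small nucleolar RNAs, which guide the modification of ribosomal RNA, 50 were higher in Col-0 capture and 2 lower (median log2 fold change 6.71), and 41 and 5 in dxo1 (median 4.14). Of 36 transfer RNA genes 25 were higher in Col-0 and 26 in dxo1, at medians of 7.28 and 6.68. These classes were looked at after the data were seen. The plastid genes named by the rule stood at 9.71 (ATCG00370), 7.99 (ATCG00060), 6.57 (ATCG00010) and 3.17 (ATCG00250) in Col-0. Whether they are transfer RNA genes was not checked, as the table used gives plastid genes no symbol. They do not stand for plastid genes in general: of the 97 tested in Col-0 capture 22 were higher and 9 lower, at a median of 0.489. Spliceosomal RNAs went both ways, 4 higher and 5 lower of 12 in Col-0.

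Transcripts that gained small RNA in dxo1 were often those with more polyA RNA there. Of 334 transcripts higher in dxo1 small RNA and tested in polyA RNA, 145 were higher in polyA RNA and 18 lower, where independent lists would share 59.5 and 46.3. The small RNA folds depended on dxo1 replicate 1: without it their median over all transcripts went from -0.305 to -1.10. High DXO1 in replicate 1 of both assays leaves open that they share plant material. The overlap would then not be independent. Scaled to the total of 21 and 22 nt counts (as CPM), EXO held 175 and 84.2 in Col-0, 15940 and 51010 in dxo1 and 11480 and 16030 in dxo1 rdr6, and GAE6 215 and 172, 26590 and 18150, and 23130 and 22230. BCS1 held 3780 and 470 in dxo1, 41.8 and 54.4 in dxo1 rdr6, from 2 and 4 counts, and 21.9 and 21.1 in Col-0. PAD4 held 105 and 29.4 in dxo1 and 0 in both dxo1 rdr6 libraries, EDS1 221 and 29.4 and likewise 0, the dxo1 replicate 2 values resting on 1 count each.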
